A study of Mus musculus with 14 samples.

How the data were processed

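RNA was measured in 14 mouse libraries: crypts of colon and ileum with both Atoh1 alleles floxed and Villin-CreERT2 (KO, 2 libraries per tissue), crypts of littermates with 1 floxed allele (WT, 2 per tissue), and live GFP-positive cells sorted from crypts of mice with an ATOH1-GFP fusion (GFP, 3 per tissue). Groups were taken from the labels. Per the labels, total RNA was purified and libraries were made by standard Illumina protocols, with the same text for all samples and no selection step named. Reads were aligned with TopHat 1.4.1 and counted per gene with HTSeq, with mm9 named as the build, per the submitters' processing notes. The HTSeq version, the annotation release and the strand setting are not given in the sources used here. The deposited values are raw whole-number counts per Ensembl gene, not normalized, with 1 table per library.

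Each table held 36536 genes, of which 31004 were given a symbol by Ensembl ID from the GENCODE M21 annotation. That annotation is of another build, so it was used for symbols, gene types, length and GC content, and no coordinates are given. The special lines of HTSeq were left out of library sizes and tests. Of uniquely placed reads, those outside genes made up 24.87, 31.92 and 30.01% in the colon GFP libraries, 52.29, 27.78 and 31.25% in the ileum GFP libraries and 9.3 to 13.25% in the crypt libraries. Of all lines together, ambiguous reads made up 0.49 to 0.71% in sorted cells and 1.03 to 1.24% in crypts. Alignments at several sites made up 29.25 to 39.6% and 33.21 to 42.98%.

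Gene counts were 12991891, 11168836 and 10498235 for colon GFP 1 to 3, 10483695 and 10768362 for colon KO, and 8848660 and 10870416 for colon WT. They were 7478418, 11885359 and 10167155 for ileum GFP 1 to 3, 10139848 and 9992947 for ileum KO, and 10426027 and 9645245 for ileum WT. Genes with a count numbered 18233 to 19377 in crypts and 17808 to 22709 in sorted cells. Counting intervals and floors cover counting error only. Replicate libraries of a group differed by far more than counting noise (chi-square per gene of 11.17 to 92.92, highest for ileum WT), and none held identical values.

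CPM are gene counts scaled to the library's gene total times its TMM factor in the fit of all 14 libraries. Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, robust fit), with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. KO against WT, the difference of that effect between tissues, and colon against ileum WT were fitted on the 8 crypt libraries (14415 genes, biological coefficient of variation 0.20). Comparisons with GFP were fitted on all 14 libraries (15274 genes, 0.23), because all groups then share 1 estimate of the spread. Sorting and genotype differ between GFP and crypt libraries and cannot be separated from cell type. TMM factors in that fit were 0.64 to 0.79 in sorted cells and 1.25 to 1.35 in crypts, since mitochondrial ribosomal RNA took a large share of the sorted-cell counts. The first principal component held 50.6% of the variance, the second 26.4% and the third 5.45%.

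The comparisons, tests, gene lists and rule for naming genes were fixed before the data were examined. There were 19 lists (goblet, Paneth, enteroendocrine, tuft, deep crypt secretory, absorptive, stem, proliferation, Notch, secretory transcription factors, ER and secretion, mucin glycosylation, antimicrobial, interferon, colon region, small intestine region, immune cells, stroma, and dissociation stress). They had 416 entries, of which 411 were matched, 2 of them by an older symbol. Each list was tested in the 10 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 190 list tests. Camera with an estimated correlation and fry, which asks whether a list moves 1 way without comparing it with other genes, were the alternatives. Genes were named by a rule. It took Atoh1 everywhere and, per comparison of 2 groups, the 6 called genes with the largest rise and the 6 with the largest fall. These needed a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and no predicted-gene symbol. It took, per list and comparison, up to 4 called members by fold change and up to 2 uncalled members by mean CPM, and any member of the Notch and secretory factor lists. Of the genes lower in KO and higher in GFP it took the 10 per tissue whose smaller log2 change was largest. For each interaction it took the 6 called genes with the largest difference in each direction, at 10 CPM or more in 1 group. The text names a part of the genes this rule admits. A fold against a group without counts is a bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval.

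Alternatives were DESeq2 size factors within edgeR, library sizes without genes above 1% of counts, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, only the libraries of the groups compared, all 14 libraries, a date tag as a block for sorted cells, and each library left out in turn. A group left with 1 library is assumed to vary like the others. Added after the data were seen were protein-coding genes only, removal of the trend with GC content and length, and leaving out both WT 2 libraries. Tested on simulated counts, edgeR recovered 72 of 100 genes changed 2-fold and 94 of 100 changed 4-fold for colon KO against WT, with 17 false calls of 183. For ileum KO against WT it recovered 62 and 95, with 16 false of 173, and for colon GFP against WT 62 and 93, with 7 false of 162. DESeq2 made 44 false calls of 216, 46 of 212 and 33 of 208 in these simulations. The changed genes were drawn from those with a mean of at least 10 CPM, and counts with each gene's fitted spread. The shares recovered therefore do not cover weaker genes or spread beyond that fit.

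Colon and ileum crypt libraries with the same number deviated together within KO (r = 0.292) and within WT (r = 0.256), across genes. They also share a library tag, so each such pair may be 1 animal, which the labels do not state. The fits reported have no block, and the fit with the pairs as a block is an alternative. The numbers do not pair KO with WT (−0.011 in colon, 0.075 in ileum). Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.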

Results

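RNA was sequenced from 14 mouse libraries in 6 groups, to ask which genes of the adult intestine depend on ATOH1, a basic helix-loop-helix transcription factor of the secretory lineage (goblet, Paneth and enteroendocrine cells). In each of colon and ileum, 2 libraries came from crypts of mice with both Atoh1 alleles floxed and the inducible epithelial recombinase Villin-CreERT2 (KO). Another 2 came from crypts of littermates with 1 floxed allele and the same recombinase, which the labels call WT. A further 3 libraries per tissue came from live GFP-positive cells sorted from crypts of mice that carry a functional ATOH1-GFP fusion protein (GFP). Gene counts ranged from 8848660 to 10870416 per crypt library and from 7478418 to 12991891 per sorted-cell library. In the sorted cells 30.02 to 44.88% of gene counts came from the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, against 0.14 to 0.22% in crypts. The labels do not state that libraries came from separate animals, so the p-values measure the spread between these samples. Values are CPM (gene counts scaled to the library's gene total times its TMM factor over all 14 libraries), given as mean ± SD with n = 3 for GFP and n = 2 for KO and WT. Calls are from edgeR at an adjusted p under 0.05.

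Atoh1 (ENSMUSG00000073043) matched the labels in every library. In colon it stood at 295, 231 and 264 CPM in the GFP libraries, 62.7 and 44.8 CPM in WT and 5.21 and 5.91 CPM in KO. In ileum the GFP libraries had 196, 323 and 296 CPM, the WT libraries 41.0 and 39.6 CPM and the KO libraries 1.02 and 0.527 CPM. Atoh1 fell by 3.28 on the log2 scale in colon KO crypts (SE 0.22; edgeR adjusted p = 0.00515) and by 5.66 in ileum KO crypts (SE 0.29; edgeR adjusted p = 0.000745). The difference between the tissues did not pass the interaction test (log2 difference 2.39, edgeR adjusted p = 0.436), but it was called without ileum WT 1 (0.0344), with no filter on low counts and with DESeq2 (adjusted p = 0.000669). The colon call was lost without colon KO 1 or colon KO 2 (highest edgeR adjusted p = 0.171).

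**Figure D1:**
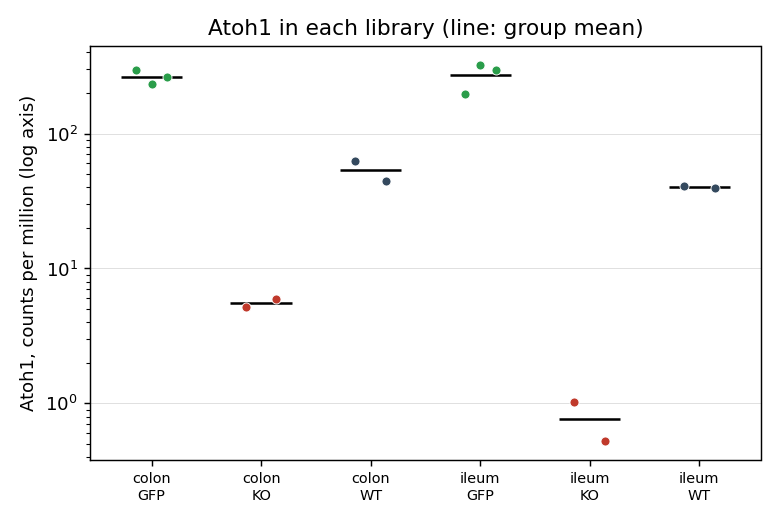
Atoh1 in CPM on a log axis, with 1 point per library and a line at each group mean. Sorted GFP-positive cells lay at 196 to 323 CPM, WT crypts at 39.6 to 62.7 CPM and KO crypts at or below 5.91 CPM.

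In colon KO crypts 3 of 20 goblet genes, 2 of 38 ER and secretion genes and 2 of 19 secretory transcription factors fell against colon WT crypts, and these calls were lost without colon KO 1 or colon KO 2. Camera called the 3 lists lower, but not with an estimated correlation (adjusted p = 0.13, 0.278 and 0.138). Fry, which does not compare a list with other genes, called them lower (fry adjusted p = 0.0151, 0.0272 and 0.0236). Tff3, a trefoil peptide of goblet cells, fell 10.3-fold, from 565 ± 83.6 to 55.3 ± 7.25 CPM (edgeR adjusted p = 0.0301). Of the regulators, Cbfa2t3, a transcriptional corepressor, fell 7.57-fold from 23.6 ± 5.27 CPM, and Gfi1, a zinc-finger repressor of the secretory lineage, fell 7.66-fold from 14.1 ± 6.36 CPM (edgeR adjusted p = 0.0128 and 0.0403). Anxa13 (ENSMUSG00000055114), an annexin of the intestinal epithelium, had the smallest p of the colon genes, at 0.642 ± 0.0127 CPM in KO against 14.1 ± 2.95 CPM in WT (log2 fold change −4.46, SE 0.21, edgeR adjusted p = 0.00143). Qpct, a glutaminyl cyclase, was the 1 gene that rose, 10.9-fold from 1.01 ± 0.168 CPM (edgeR adjusted p = 0.0403).

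The other called genes of the naming rule were Bcas1 (6.83-fold lower) and Sytl2, a synaptotagmin-like protein of vesicle traffic (4.4-fold lower), from the goblet list. Also lower in KO were the chemokine Ccl6 (6.93-fold), the anoctamin Ano7 (6.27-fold), Hepacam2 (8.84-fold), the tyrosine-catabolic enzyme Hpd (9.23-fold), Slc12a8 (8.39-fold) and Sval1 (7.84-fold). Among the 20 goblet genes tested, 3 fell over all genes tested and 17 adjusted over the list alone, with a median log2 fold change of −2.68 (camera adjusted p = 7.08e-60, but adjusted p = 0.13 with an estimated correlation). The abundant mucus genes Clca1 (529 ± 68.2 against 6020 ± 4790 CPM) and Fcgbp (450 ± 54.1 against 5060 ± 2520 CPM) did not pass (edgeR adjusted p = 0.321 and 0.211). Clca1 stood at 2636 and 9409 CPM in the WT libraries. Of 38 ER and secretion genes the disulfide isomerases Pdia5 (2.76-fold) and Txndc5 (2.51-fold) fell. Adjusted over the list alone 31 did, and the median was −0.46 (adjusted p = 0.278 with an estimated correlation). Of 19 secretory transcription factors 2 fell, 11 adjusted over the list alone, where 1 rose (median −1.24, adjusted p = 0.138 with an estimated correlation). Spdef, an Ets factor of goblet and Paneth cells, had 17.7 ± 2.27 against 110 ± 23.1 CPM and Bhlha15, a factor of secretory cell maturation, 1.07 ± 0.122 against 8.98 ± 0.563 CPM (edgeR adjusted p = 0.124 and 0.172). Neurog3, the endocrine determination factor, had no count in colon KO and 1.87 ± 0.419 CPM in WT, at least 17.5-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0953). Spdef, Bhlha15 and Neurog3 were called with DESeq2, with the 4 colon libraries alone and with all 14 libraries, Spdef and Bhlha15 also without both WT 2 libraries and Neurog3 with no filter on low counts. Clca1 and Fcgbp were called with DESeq2.

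Members of the other secretory lists did not pass over all genes tested in colon KO crypts. Adjusted over the list alone, 6 of 25 enteroendocrine genes fell (median −0.72, adjusted p = 0.138 with an estimated correlation), and 3 of 7 deep crypt secretory genes did (median −1.08, adjusted p = 0.141). By the same measures 11 of 26 mucin glycosylation genes fell while 1 rose (median −0.37, adjusted p = 0.148). Of 16 Paneth genes 1 fell (median −2.88, or −2.20 with genes near the floor at their bound, adjusted p = 0.327 with an estimated correlation). Camera also called the tuft list lower (median −1.07, adjusted p = 0.816 with an estimated correlation), the immune cell list lower (median −0.95, adjusted p = 0.733) and the absorptive list higher (median 0.28, adjusted p = 0.733). These lists differed between the WT libraries: in colon WT 2 all 15 tuft genes were higher than in colon WT 1 (median log2 ratio 1.10), as were 2 of 28 absorptive genes (−1.09) and 6 of 25 immune genes (−0.46). Without colon WT 2 the KO medians were −0.40 for tuft, −0.10 for absorptive and −1.05 for immune genes, and without colon WT 1 they were −1.49, 0.78 and −0.54. The proliferation list was called higher (median 0.19, 6 of 26 adjusted over the list alone, adjusted p = 0.446 with an estimated correlation). The Notch, stem, antimicrobial, interferon, colon region, small intestine region, stroma and dissociation lists were not called. The Notch target Hes1 had 48.2 ± 4.49 against 55.5 ± 8.85 CPM (edgeR adjusted p = 0.863).

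In all 22 of 14415 genes tested were called in colon KO crypts, 1 higher and 21 lower, and 1108 had an unadjusted p under 0.05. The count was 157 with DESeq2, 102 with the 4 colon libraries alone, 73 with all 14 libraries in the fit and 56 with no filter on low counts. Without colon KO 1 or colon KO 2 edgeR called 0 genes (791 and 624 at an unadjusted p under 0.05; DESeq2 was run on all libraries only). Without colon WT 1 it called 14 and without colon WT 2 it called 4, of which Ano7, Anxa13 and Atoh1 are named above. Without colon WT 1 the calls of Tff3, Bcas1, Sytl2, Hpd, Sval1, Ccl6 and Qpct were lost (edgeR adjusted p of 0.0909 to 0.209). Other settings ended the calls of Tff3 (without both WT 2 libraries), Slc12a8 and Ccl6 (no filter on low counts) and Pdia5 and Txndc5 (all 14 libraries). Slc12a8 and Txndc5 lost theirs with the GC and length trend removed, and Txndc5 with DESeq2 size factors. With the replicate number as a block Bcas1, Sytl2, Gfi1, Ccl6, Txndc5 and Qpct, the 1 gene that rose, lost theirs.

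In ileum KO crypts 12 of 20 goblet genes, 4 of 16 Paneth genes, 7 of 25 enteroendocrine genes and 6 of 19 secretory transcription factors fell. Camera called these lists lower, but not with an estimated correlation (adjusted p = 0.0762, 0.148, 0.0762 and 0.138). Fry, which does not compare a list with other genes, called them lower (fry adjusted p = 0.00406, 0.0224, 0.00242 and 0.0125). The chloride channel regulator Clca1 fell from 5070 ± 3650 to 54.7 ± 30.3 CPM, Tff3 from 753 ± 28.8 to 30.9 ± 14.9 CPM, and Agr2, a disulfide isomerase needed for mucin folding, from 956 ± 362 to 44.7 ± 21.3 CPM (edgeR adjusted p = 0.0468, 0.00484 and 0.0151). Spdef fell 41.5-fold, from 67.3 ± 35.2 to 1.58 ± 0.639 CPM (log2 fold change −5.38, SE 0.52, edgeR adjusted p = 0.0142). Gcg, which encodes proglucagon, fell 5.46-fold to 7.89 ± 0.546 CPM (edgeR adjusted p = 0.00179). Plb1, a brush border phospholipase, rose 3.38-fold to 109 ± 10.5 CPM, and Mme, which encodes the brush border peptidase neprilysin, rose 3.17-fold to 164 ± 49 CPM (edgeR adjusted p = 0.0218 and 0.022).

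By list, 12 of 20 goblet genes fell, all 20 adjusted over the list alone, with a median log2 fold change of −4.48 (adjusted p = 0.0762 with an estimated correlation). These included the calpain Capn9 (56.7-fold) and Rep15, a Rab15 effector (54.3-fold). Of 19 secretory transcription factors 6 fell, 12 adjusted over the list alone (median −1.69, adjusted p = 0.138 with an estimated correlation), among them Creb3l4 (18.1-fold), Cbfa2t3 (17.5-fold), the endocrine factor Insm1 (10.9-fold), Bhlha15 (9.09-fold) and Gfi1 (8.94-fold). Of 16 Paneth genes 4 fell, 15 adjusted over the list alone (median −4.96, adjusted p = 0.148 with an estimated correlation): Copz2 (28.6-fold), Habp2 (20.4-fold), Defa22 (14.7-fold) and Defa29 (13.3-fold). The defensins are uncertain because near-identical copies share reads. The Paneth list also differed between the WT libraries, with 14 of 16 genes higher in ileum WT 2 than in ileum WT 1 (median log2 ratio 2.53), and its KO median was −3.60 without ileum WT 2 and −5.54 without ileum WT 1. Of 25 enteroendocrine genes 7 fell, 19 adjusted over the list alone (median −2.24, adjusted p = 0.0762 with an estimated correlation), including Cck (7.61-fold) and Tph1, the enzyme of serotonin synthesis (6.8-fold). Of 38 ER and secretion genes 4 fell, 13 adjusted over the list alone (median −0.38, adjusted p = 0.446 with an estimated correlation). The falls were 10.6-fold for Kdelr3, 3.16-fold for Txndc5 and 1.55-fold for the signal peptidase subunit Sec11c. The O-glycosylation genes Galnt5 (11.8-fold) and Galnt12 (2.76-fold) and the fucosyltransferase Fut2 (2.98-fold) fell among 26 mucin glycosylation genes. Adjusted over the list alone 9 were lower and 2 higher (median −0.33, adjusted p = 0.3 with an estimated correlation).

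The Notch ligand Dll1 fell 2.29-fold to 9.48 ± 2.24 CPM (edgeR adjusted p = 0.0442) and was the 1 called member of the deep crypt secretory list and of the Notch list. Adjusted over the list alone, 6 of 7 deep crypt secretory genes were lower (median −1.87, adjusted p = 0.232 with an estimated correlation). In the Notch list 3 were higher and 1 lower adjusted over the list alone. Hes1 had 29.4 ± 0.524 against 35.4 ± 3.52 CPM (edgeR adjusted p = 0.547). Smoc2, a stem cell marker, rose 1.49-fold (edgeR adjusted p = 0.0429), while Olfm4, another, had 456 ± 334 against 1200 ± 86.8 CPM (edgeR adjusted p = 0.46). Others that fell were Fer1l6 (51.9-fold), Ano7 (36.2-fold) and the carboxylesterase Ces1c, with 3 counts in KO (ratio 116, counting interval 39.8 to 564). Others that rose were Gprc5a (3.32-fold), adenosine deaminase Ada (2.84-fold), Ahcy (2.35-fold) and the claudin Cldn4 (2.32-fold). Adjusted over the list alone, 5 absorptive (median 0.56), 9 proliferation (median 0.31) and 3 small intestine region genes (median 0.79) rose (adjusted p = 0.487, 0.445 and 0.454 with an estimated correlation). Tuft genes had a median of −4.48, with 12 of 15 lower adjusted over the list alone (adjusted p = 0.471 with an estimated correlation). They differed between the WT libraries: Dclk1 stood at 4.58 CPM in ileum WT 1 and 84.4 CPM in ileum WT 2, and Trpm5 at 6.18 and 72.5 CPM. Without ileum WT 2 the tuft median was −1.40, and without ileum WT 1 it was −5.39 with 14 genes lower. The immune list, not called (median −0.45 although camera gave it a direction up), had a median of 2.02 without ileum WT 1 and −1.13 without ileum WT 2.

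In ileum 176 of 14415 genes were called, 19 higher and 157 lower. The count was 496 with DESeq2, 265 with all 14 libraries and 4 with the 4 ileum libraries alone, 12 without ileum KO 1 and 11 without ileum KO 2, and 1348 without ileum WT 1. Atoh1, Tff3, Gprc5a, Gcg and Ano7 kept their calls without any 1 of the 4 ileum libraries. Mme lost its call without ileum KO 1. The other genes named lost theirs without ileum KO 1 (edgeR adjusted p of 0.0676 to 0.226) and without ileum KO 2 (0.0841 to 0.313). Clca1, Fer1l6, Cck, Sec11c, Smoc2, Ada and Cldn4 also lost theirs without ileum WT 2 (edgeR adjusted p of 0.0503 to 0.156). With the 4 ileum libraries alone the genes named lost their calls except Atoh1, Ano7 and Gcg. With all 14 libraries Defa22, Defa29, Tph1, Cck, Sec11c, Dll1, Smoc2, Plb1 and Cldn4 lost theirs, and with no filter on low counts Clca1, Capn9, Fer1l6, Creb3l4, Bhlha15 and Defa22. Without both WT 2 libraries Clca1, Sec11c, Smoc2 and Mme lost theirs. With the replicate number as a block Clca1, Agr2, Fer1l6, Creb3l4, Insm1, Bhlha15, Defa22, Tph1, Cck, Sec11c, Dll1, Smoc2, Ahcy and Cldn4 did. Dclk1 and Trpm5, not called, were called with DESeq2 and without ileum WT 1, and Dclk1 without both WT 2 libraries. Called goblet genes went from 12 to 2 without either KO library, enteroendocrine genes from 7 to 2 and 1, and Paneth genes from 4 to 12 without ileum WT 1 and 7 without ileum WT 2.

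**Figure D2:**
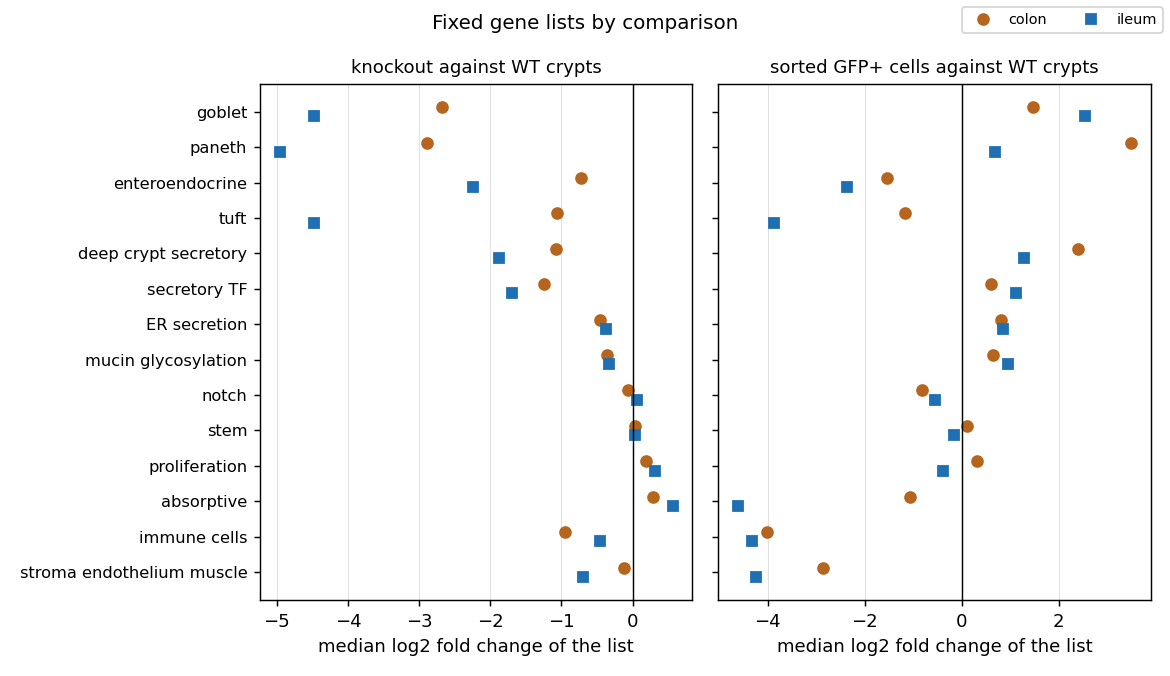
Median log2 fold change of each fixed gene list, with circles for colon and squares for ileum, in knockout against WT crypts (left) and sorted GFP-positive cells against WT crypts (right). Goblet genes had medians of −2.68 and −4.48 in the knockouts and 1.47 and 2.53 in the sorted cells, and enteroendocrine genes lay below 0 in all 4 comparisons.

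The interaction test asked which genes responded differently to the knockout in colon and ileum. Anxa13 was the 1 gene called of 14415 (563 had an unadjusted p under 0.05). Anxa13 was 0.642 ± 0.0127 CPM in colon KO against 14.1 ± 2.95 CPM in colon WT, while ileum KO libraries had 182 and 175 CPM and ileum WT libraries 115 and 112 CPM (interaction log2 −5.15, SE 0.25, edgeR adjusted p = 0.00179). Adjusted over the list alone, 15 of 20 goblet genes fell less in colon than in ileum (median interaction 1.98, adjusted p = 0.138 with an estimated correlation), as did 5 enteroendocrine genes (median 1.06, adjusted p = 0.138). Atoh1 itself was left at 5.21 and 5.91 CPM in colon KO (WT 62.7 and 44.8 CPM). In ileum KO it was left at 1.02 and 0.527 CPM (WT 41 and 39.6 CPM), a larger fall, although this test did not call the difference. Smaller falls in colon can therefore not be told apart from the Atoh1 left there. Camera called the tuft (median 3.90), Paneth (median 2.28) and secretory transcription factor lists (median 0.45) in the same direction (adjusted p = 0.446, 0.446 and 0.445 with an estimated correlation), beside the tuft and Paneth values of ileum WT 2 given above. It called the absorptive (median −0.34), small intestine region (median −0.84) and immune cell lists (median −0.16) in the opposite direction (adjusted p = 0.733, 0.53 and 0.734 with an estimated correlation). The count was 2 with same-numbered colon and ileum libraries of a genotype as a block, 52 with DESeq2, 9 with no filter on low counts, 313 without ileum WT 1 and 4 without ileum WT 2. Without colon KO 1 or colon KO 2 edgeR called 0 genes (446 and 372 at an unadjusted p under 0.05) and Anxa13 had an adjusted p of 0.079 and 0.0805. Among protein-coding genes, a set without Anxa13, edgeR called 0 (516 at an unadjusted p under 0.05).

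In sorted colon GFP-positive cells 14 of 20 goblet, 4 of 7 deep crypt secretory and 23 of 38 ER genes were higher than in whole WT crypts, and 13 of 28 absorptive, 12 of 25 enteroendocrine and 18 of 25 immune genes were lower. None of these camera list calls held with an estimated correlation (adjusted p of 0.446 or more). Muc2, the gel-forming mucin, stood at 33100 ± 1910 against 1070 ± 706 CPM (log2 fold change 4.95, SE 0.70, edgeR adjusted p = 0.000106). Agr2 rose 12.1-fold to 14900 ± 2030 CPM, the kallikrein Klk1 14.1-fold to 5260 ± 488 CPM and Spink4 7.53-fold to 4340 ± 624 CPM. Aqp8, a water channel of surface colonocytes, fell from 307 ± 130 to 2.82 ± 2.99 CPM and the chloride exchanger Slc26a3 from 639 ± 175 to 17.5 ± 14.8 CPM (edgeR adjusted p = 9.36e-06 and 8.89e-05).

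Of the 20 goblet genes 14 rose in the colon (14 adjusted over the list alone; median 1.47, adjusted p = 0.523 with an estimated correlation), while Clca1 (4180 ± 794 against 6020 ± 4790 CPM) and Fcgbp (2730 ± 343 against 5060 ± 2520 CPM) did not pass. Among deep crypt secretory genes, those of colon secretory cells next to stem cells, Kit rose 7.09-fold and Cd24a 6.3-fold. Of the 7 genes 4 rose (5 adjusted over the list alone; median 2.40, adjusted p = 0.446 with an estimated correlation). Reg4 had 2820 ± 653 against 318 ± 272 CPM (edgeR adjusted p = 0.104), but was called with no filter on low counts, with DESeq2, with the 5 libraries compared alone and without both WT 2 libraries. Fcgbp was called with no filter and with those 5 libraries. Of 38 ER and secretion genes 23 rose (23 adjusted over the list alone; median 0.81, adjusted p = 0.547 with an estimated correlation), Kdelr2 by 3.95-fold. Cbfa2t3 (4.3-fold), Gfi1 (3.13-fold) and Spdef (3.04-fold) rose, Klf4 (3.47-fold) and Hes1 (2.71-fold) fell, and Dll1 rose 2.38-fold. Paneth list members also rose, 6 of 16 (6 adjusted over the list alone; median 3.48, adjusted p = 0.733 with an estimated correlation), among them Mptx1 (18300 ± 6960 against 1170 ± 776 CPM) and Clps (19.6-fold). The median was 0.77 without colon GFP 1, a library that held ileal transcripts (Lyz1 at 1434 CPM, against 37.8 and 42.0 CPM in colon GFP 2 and 3). Slc15a1 (32.5-fold) and Car4 (38.4-fold) fell with 13 of 28 absorptive genes while 1 rose (13 and 2 adjusted over the list alone; median −1.08, or −0.82 at the bounds, and −2.0 without colon GFP 1; adjusted p = 0.501 with an estimated correlation). Of 25 enteroendocrine genes 12 fell, Cpe by 15.1-fold, and 2 rose (the same counts adjusted over the list alone; median −1.54, adjusted p = 0.446 with an estimated correlation).

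Genes of other cells were lower after sorting: 18 of 25 immune genes (19 adjusted over the list alone; median −4.01, or −3.83 at the bounds), with the macrophage lysozyme Lyz2 at 0.6 ± 0.597 against 44.9 ± 17.9 CPM. Likewise 11 of 21 stroma genes were lower (16 adjusted over the list alone; median −2.87, or −2.98 at the bounds). Antimicrobial and interferon genes, whose cells of origin were not tested, were also lower. Of 18 antimicrobial genes 12 fell (13 adjusted over the list alone, median −2.72, or −2.61 at the bounds), Saa1 by 45.5-fold. Of 21 interferon genes 14 fell (14 adjusted over the list alone, median −1.18). With an estimated correlation the immune, stroma, antimicrobial and interferon lists had camera adjusted p = 0.487, 0.469, 0.481 and 0.602. The largest rises were in RNA classes that preparation can alter, Hist1h4d (193 ± 138 against 0.155 ± 0.0258 CPM), Rn7sk (474 ± 193 against 0.664 ± 0.164 CPM) and mt-Rnr2 (459000 ± 73300 against 930 ± 190 CPM). Histone genes share reads and are uncertain. Hnrnpa0 fell to 0.162 ± 0.0455 CPM from 73.6 ± 4.36 CPM. Its log2 fold change was alike in colon and ileum sorted cells (−8.70 and −8.90). Whether it reflects the cells or the way sorted libraries were made was not tested. In all 7005 of 15274 genes were called, 3403 higher and 3602 lower, and 4298 without colon WT 1. Without that library goblet calls numbered 9, ER calls 14, interferon calls 6 and Paneth calls 2 (3 without colon WT 2, 10 without colon GFP 3). Spdef, Mptx1, Clps and Dll1 also lost their calls without it (edgeR adjusted p = 0.0673, 0.115, 0.0618 and 0.184), and Dll1 without colon WT 2 (0.147) or colon GFP 1 (0.185), with the 5 libraries compared alone and without both WT 2 libraries.

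In ileum GFP-positive cells 17 of 20 goblet genes and 12 of 19 secretory transcription factors were higher than in WT crypts, and 24 of 28 absorptive genes were lower. None of these camera list calls held with an estimated correlation (adjusted p of 0.138 or more). Muc2 rose 40.9-fold to 16900 ± 7520 CPM, the lectin Zg16 31.4-fold to 25500 ± 13400 CPM and Tff3 10.9-fold to 8180 ± 3980 CPM (edgeR adjusted p = 5.04e-05, 0.0002 and 8.96e-05). The bile acid transporter Slc10a2 fell from 169 ± 102 to 0.649 ± 0.348 CPM, the apolipoprotein Apoa4 from 159 ± 54 to 1.34 ± 1.27 CPM and the amino acid transporter Slc6a19 from 376 ± 65.4 to 4.34 ± 0.306 CPM. Of 28 absorptive genes 24 fell and 1 rose (25 and 1 adjusted over the list alone; median −4.62, adjusted p = 0.138 with an estimated correlation).

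Of 20 goblet genes 17 rose and 1 fell in the ileum (the same adjusted over the list alone; median 2.53, adjusted p = 0.446 with an estimated correlation), Agr2 by 17.6-fold, while Clca1 had 11600 ± 6170 against 5070 ± 3650 CPM (edgeR adjusted p = 0.15), and was called with no filter on low counts, without ileum WT 2 and without both WT 2 libraries. Of 19 secretory transcription factors 12 rose and 3 fell (the same adjusted over the list alone; median 1.12, adjusted p = 0.446 with an estimated correlation). Cbfa2t3 (8.41-fold), Creb3l1 (6.32-fold), Gfi1 (6.29-fold) and Spdef (3.26-fold) rose and Insm1 fell 3.14-fold. Dll1 rose 5.91-fold, Kit 6.52-fold and Cd24a 2.43-fold. Of 7 deep crypt secretory genes 6 were higher (6 adjusted over the list alone; median 1.28, adjusted p = 0.471 with an estimated correlation). Hes1 fell 2.71-fold. ER and secretion genes rose in 24 of 38 cases (24 adjusted over the list alone; median 0.85, adjusted p = 0.592 with an estimated correlation). The Paneth lysozyme Lyz1 (44000 ± 12200 against 5270 ± 425 CPM) and Defa24 (10300 ± 2300 against 6130 ± 6200 CPM) did not pass (edgeR adjusted p = 0.11 and 0.74), but Lyz1 was called with no filter on low counts, with DESeq2, with the replicate block and with the 5 libraries compared alone. Of 16 Paneth genes 2 rose (1 adjusted over the list alone; list not called). Of 25 enteroendocrine genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; median −2.37, adjusted p = 0.431 with an estimated correlation), Nts by 68-fold and Cpe by 45.2-fold. Tuft genes fell in 10 of 15 cases (10 adjusted over the list alone), but in 1 without ileum WT 2 (median −3.87 and −0.80). Immediate early genes were higher, Egr1 by 44-fold, Fosb by 75-fold and Dusp1 by 24.6-fold. The dissociation list had 11 members higher and 4 lower (the same adjusted over the list alone; median 1.75, adjusted p = 0.561 with an estimated correlation).

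Immune genes fell in 23 of 25 cases (24 adjusted over the list alone; median −4.32, or −4.10 at the bounds) and stroma genes in 17 of 21 (17; median −4.25, or −3.84 at the bounds), with adjusted p = 0.628 and 0.58 with an estimated correlation. Without ileum WT 1 the counts were 9 and 7. Rn7sk stood at 340 ± 96.2 against 0.79 ± 0.177 CPM and mt-Rnr2 at 330000 ± 28800 against 1070 ± 146 CPM. Hist1h4d, with 2 counts in WT, had a ratio of 1660 (counting interval 459 to 13700), and Hnrnpa0 fell to 0.177 ± 0.155 from 96.1 ± 6.09 CPM. In all 8059 genes were called, 3759 higher and 4300 lower. Cd24a and Insm1 lost their calls without ileum WT 1 (edgeR adjusted p = 0.119 and 0.0515) and with the 5 libraries compared alone, and Insm1 with the GC and length trend removed or the replicate number as a block.

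Genes that were both lower in KO and higher in GFP were then listed for each tissue. In colon 17 of the 21 genes lower in KO were also higher in GFP, where independent lists would share 4.22. Another 1 was lower in GFP, where they would share 5.24. Among these 17, Ccl6 rose 6.19-fold in GFP, Hpd 5.98-fold, Anxa13 5.48-fold, Sval1 5.47-fold, Hepacam2 4.41-fold, Slc12a8 4.26-fold and Ano7 4.11-fold, next to Atoh1, Cbfa2t3, Gfi1, Bcas1, Sytl2, Pdia5 and Txndc5. In ileum 117 of 157 genes lower in KO were higher in GFP (35.3 for independent lists) and 13 were lower (46.7). In turn 13 of the 19 genes higher in KO were lower in GFP (5.66). These 117 included P2ry4, a nucleotide receptor (7.14 ± 4.57 CPM in WT, 374 ± 74.4 CPM in GFP), the potassium channel Kcnma1 (18.6-fold), the chemokine Ccl9 (13.8-fold) and Ano7 (12.0-fold). Lower in KO in both tissues were 16 genes, where independent lists would share 0.229, although same-numbered colon and ileum libraries deviated together and may come from the same animals. They were Atoh1, Tff3, Bcas1, Sytl2, Ccl6, Cbfa2t3, Gfi1, Ano7, Hepacam2, Hpd, Slc12a8, Sval1, Pdia5, Txndc5 and, named after their values were seen, Rapgef3 and Gm3054. Of the 176 genes called in ileum 168 had the same sign in colon, and of the 22 called in colon 20 had the same sign in ileum.

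Both comparisons of a tissue used the same 2 WT libraries, which cannot be split further. Across genes, which are not independent replicates, the fold changes correlated at r = −0.051 in colon and 0.028 in ileum. In 20 simulations without differences between the groups of a tissue, r was 0.542 and 0.521. The simulations redrew every library, WT included, gene by gene from rates pooled over the tissue's groups. They do not hold the real WT libraries, so they do not measure what those libraries add to both comparisons. The covariance of the fold changes was −0.039 and 0.041, against 0.146 and 0.151 in the simulations (differences −0.185 and −0.111). The colon overlap was 0 without colon KO 1 or colon KO 2, 8 without colon WT 1, 3 without colon WT 2 and 101 with DESeq2. The ileum overlap was 7 without either KO library, 241 without ileum WT 1 and 234 with DESeq2. The overlap of both tissues was 0 without either colon KO library, 10 without colon WT 1, 3 without colon WT 2, 6 without either ileum KO library, 71 without ileum WT 1, 55 without ileum WT 2 and 100 with DESeq2. In the sorted cells of both tissues, 2496 genes were higher than in WT crypts (837 for independent lists) and 2782 lower (1014), while 43 and 21 went opposite ways. All sorted libraries also differed from all crypt libraries in sorting and in mitochondrial ribosomal RNA (30.02 to 44.88% against 0.14 to 0.22% of gene counts). Such shared differences enter both lists, so the excess over independent lists does not measure a shared cell type alone.

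**Figure D3:**
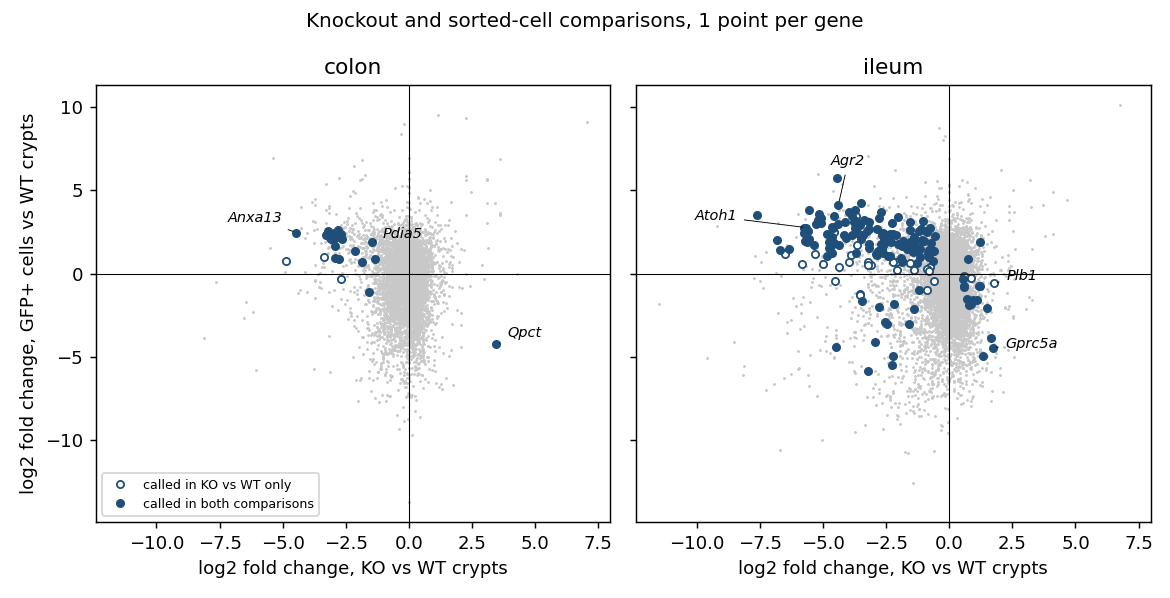
Log2 fold change in KO against WT crypts (horizontal) and in sorted GFP-positive cells against WT crypts (vertical), 1 grey point per gene, fitted values; outlined circles passed the KO test and filled circles both tests. Most called genes lie in the upper left, 17 of the 22 in colon and 117 of the 176 in ileum.

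Sorted cells were also compared with KO crypts. In colon Muc2 was 33100 ± 1910 CPM in GFP and 234 ± 66.1 CPM in KO (log2 fold change 7.14, SE 0.78, edgeR adjusted p = 1.01e-05), and in ileum 16900 ± 7520 against 21.2 ± 16.5 CPM (9.64, SE 0.87, edgeR adjusted p = 1.43e-06). Atoh1 was 47.3-fold higher in colon and 349-fold higher in ileum. In colon Agr2 (51.8-fold), Spink4 (48.6-fold), Cbfa2t3 (32.3-fold), Bhlha15 (28.2-fold), Gfi1 (23.8-fold), Kit (19.8-fold) and Mptx1 (297-fold) were higher. The sodium-proton exchanger Slc9a3 (1.13 ± 1.24 against 207 ± 69.6 CPM) and Aqp8 (2.82 ± 2.99 against 451 ± 2.79 CPM) were lower. In ileum Zg16 (785-fold), Agr2 (376-fold), Cbfa2t3 (150-fold), Spdef (138-fold), Creb3l4 (92.8-fold), Kdelr3 (53.7-fold) and P2ry4 (374 ± 74.4 against 0.31 ± 0.225 CPM) were higher. Slc10a2 (440-fold), Apoa4 (261-fold) and Slc6a19 (174-fold) were lower.

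All 20 goblet genes were higher in colon (median 3.88, adjusted p = 0.284 with an estimated correlation) and 19 of 20 in ileum (median 7.24, adjusted p = 0.148), with the same counts adjusted over the list alone. ER and secretion genes were higher in 34 of 38 (36 adjusted over the list alone; median 1.33, adjusted p = 0.446) and 29 of 38 cases (30; median 1.24, adjusted p = 0.487). All 7 deep crypt secretory genes were higher in both tissues (7 adjusted over the list alone; medians 3.65 and 3.72, adjusted p = 0.284 and 0.313), all with an estimated correlation. Enteroendocrine lists were not called, with 3 genes higher and 8 lower in colon and 4 and 6 in ileum (the same adjusted over the list alone). In colon 7452 and in ileum 8477 of 15274 genes were called. Without colon KO 2 the colon ER count was 22, and Reg4 (2820 ± 653 against 22.6 ± 6.4 CPM, edgeR adjusted p = 0.01) lost its call without colon KO 1 (0.0648) or colon KO 2 (0.0765).

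Between colon and ileum GFP-positive cells 11 of 12 colon region genes were higher in colon and 13 of 16 Paneth genes lower, and the camera call of the Paneth list was lost with an estimated correlation (adjusted p = 0.436). Atoh1 did not pass (264 ± 32 against 272 ± 67.3 CPM, edgeR adjusted p = 0.901). The homeobox gene Hoxb13 was 110 ± 37.1 CPM in colon and 0.531 ± 0.919 CPM in ileum, and Gata4, a small intestinal factor, 0.287 ± 0.186 against 15.4 ± 10.4 CPM (edgeR adjusted p = 5.4e-06 and 0.000455). Fut2, an alpha-1,2-fucosyltransferase, was 433 ± 37.5 against 8.87 ± 1.74 CPM (edgeR adjusted p = 2.3e-09). B3gnt6, the mucin core 3 enzyme, was 60.1-fold higher in colon, and Fut9, without a count in ileum, at least 130-fold higher against a floor of 3 counts over the group. Colon region genes were higher in colon in 11 of 12 cases (11 adjusted over the list alone; median 5.69, or 4.13 at the bounds), and this list kept its camera call with an estimated correlation (adjusted p = 0.0179). It and the same list in WT crypts were the only camera calls, of 190 list tests, that held with an estimated correlation.

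Among goblet genes Retnlb (219-fold) and Klk1 (4.28-fold) were higher in colon cells and Tff3 (7.24-fold) and Fcgbp (4.81-fold) lower. Of the 20 genes 2 were higher and 7 lower (3 and 8 adjusted over the list alone; list not called; 3 lower without colon GFP 2 or ileum GFP 2, and 4 without ileum GFP 3). Bhlha15 (5.17-fold), Dll1 (3.93-fold), Klf4 (1.87-fold), Lgr5 (3.83-fold), Krt20 (12.4-fold) and Lyz2 (22.5-fold) were higher in ileum cells. Olfm4 stood at 535 ± 462 CPM there against 6.96 ± 10.1 CPM in colon, of which colon GFP 1 held 18.6 CPM and the others 0.623 and 1.65 CPM. Paneth genes were lower in colon in 13 of 16 cases and higher in 2 (the same adjusted over the list alone; median −5.80, and −7.80 without colon GFP 1; adjusted p = 0.436 with an estimated correlation), Defa22 by 141-fold and Defa24 by 98.2-fold. Mucin glycosylation genes were mixed, with 8 higher and 3 lower (9 and 4 adjusted over the list alone), a median of −0.10, a mean of 1.08 and a camera call up (adjusted p = 0.53 with an estimated correlation). Absorptive genes included Car1 (869-fold higher in colon) and Sis (11.2-fold lower), with 4 higher and 9 lower of 28 (4 and 15 adjusted over the list alone; median −1.49, adjusted p = 0.561 with an estimated correlation). Reg4 (2820 ± 653 against 571 ± 84.5 CPM) did not pass (edgeR adjusted p = 0.193). Nxpe2 was 451-fold higher in colon. In all 3471 genes were called, 1919 higher in colon and 1552 lower, and 2147 with the 6 sorted libraries alone. Defa24 lost its call without any library but colon GFP 1 (edgeR adjusted p of 0.0633 to 0.0727), Fcgbp without colon GFP 2, colon GFP 3 or ileum GFP 2 (0.0553 to 0.0592), and Sis without colon GFP 3 (0.0535) or ileum GFP 2 (0.0525). Only colon GFP 1 with ileum GFP 2, and colon GFP 2 with ileum GFP 3, share a date tag. The fit with this tag as a block compares the tissues within these pairs alone, and colon GFP 1 held ileal transcripts. In that fit Retnlb (edgeR adjusted p = 0.0735), Fcgbp (0.0797), Olfm4 (0.0864), Defa22 (0.0922), Defa24 (0.234), Lyz2 (0.103), Sis (0.094) and Car1 (0.0573) lost their calls. Olfm4, Sis, Defa24, Defa22 and Lgr5 lost theirs with the 6 sorted libraries alone, where Reg4 was called, as it was with no filter on low counts. The replicate number as a block also ended the calls of Fcgbp and Sis.

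Between colon and ileum WT crypts 11 of 12 colon region and 11 of 21 interferon genes were higher in colon, and 20 of 28 absorptive and 20 of 26 proliferation genes lower. With an estimated correlation the camera call held for the colon region list (adjusted p = 0.019) but not for the interferon, absorptive and proliferation lists (adjusted p = 0.446, 0.21 and 0.313). Aqp8 stood at 307 ± 130 CPM in colon and 0.159 ± 0.00979 CPM in ileum, and Hoxb13 at 177 ± 4.91 CPM in colon with 1 count in ileum (ratio 4440, counting interval 797 to 175000). Sucrase-isomaltase, Sis, was 1620 ± 146 CPM in ileum and 3.99 ± 2.93 CPM in colon, Apoa1 1640 ± 28.6 against 2.36 ± 2.18 CPM, and Olfm4 1200 ± 86.8 against 2.19 ± 1.93 CPM (edgeR adjusted p = 0.000249, 0.000412 and 0.00223). Of 26 proliferation genes 20 were lower in colon (23 adjusted over the list alone; median −0.70, adjusted p = 0.313 with an estimated correlation), Top2a by 2.15-fold and Birc5 by 2.13-fold. Of 21 interferon genes 11 were higher (15 adjusted over the list alone; median 1.65, adjusted p = 0.446 with an estimated correlation), Oas2 by 6.87-fold and Rtp4 by 5.6-fold. This count was 7 without colon WT 1 and 17 without ileum WT 1.

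Atoh1 did not pass between the WT crypts (53.7 ± 12.7 against 40.3 ± 1.01 CPM, edgeR adjusted p = 0.177). Creb3l1 (3.3-fold), Foxa2 (4.9-fold), Klf4 (3.32-fold) and the mucin enzyme B3gnt7 (7.59-fold) were higher in colon and Bhlha15 (5.1-fold) and Lgr5 (3.82-fold) lower. Goblet genes were higher in 4 of 20 cases (4 adjusted over the list alone; median 0.56, adjusted p = 0.752 with an estimated correlation; 8 without ileum WT 2, 2 without colon WT 1 and 1 without colon WT 2). They included Klk1 (4.34-fold) and Bcas1 (1.87-fold). Absorptive genes were lower in 20 of 28 and higher in 3 cases (22 and 3 adjusted over the list alone; median −3.15, adjusted p = 0.21 with an estimated correlation). Paneth genes were lower in 12 of 16 (12 lower and 1 higher adjusted over the list alone; median −7.99, adjusted p = 0.367) and small intestine region genes, Apoa4 among them (155-fold), lower in 10 of 14 (12; median −3.55, adjusted p = 0.141), all with an estimated correlation. Mptx2 was 1.69 ± 1.53 against 1920 ± 1500 CPM. Colon region genes were higher in 11 of 12 cases (11 adjusted over the list alone; median 8.45, or 4.93 at the bounds; adjusted p = 0.019 with an estimated correlation). Car1 (415-fold higher) and Defa24 (4.89 ± 6.33 against 6130 ± 6200 CPM) lost their calls with the same-numbered colon and ileum libraries as a block (edgeR adjusted p = 0.0524 and 0.0862). In all 2872 of 14415 genes were called, 1472 higher in colon and 1400 lower, against 1213 with the 4 WT libraries alone, 1836 with all 14 libraries, 1468 without colon WT 1 and 1314 without colon WT 2. Bhlha15 lost its call without colon WT 1 (0.0908) or colon WT 2 (0.0836). Klk1 lost it without colon WT 1 (0.0908), colon WT 2 (0.192) or ileum WT 1 (0.0774), and Bcas1 without colon WT 1 (0.118), colon WT 2 (0.147) or ileum WT 2 (0.0551), all edgeR adjusted p. Olfm4, Mptx2 and Bcas1 lost their calls without both WT 2 libraries (edgeR adjusted p = 0.104, 0.076 and 0.158), and Lgr5 (0.0508) and Bcas1 with all 14 libraries. With the 4 WT libraries alone Creb3l1 (0.0502), Bhlha15, Klk1 and Defa24 lost theirs, and with no filter on low counts Klk1 and Defa24.

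**Figure D4:**
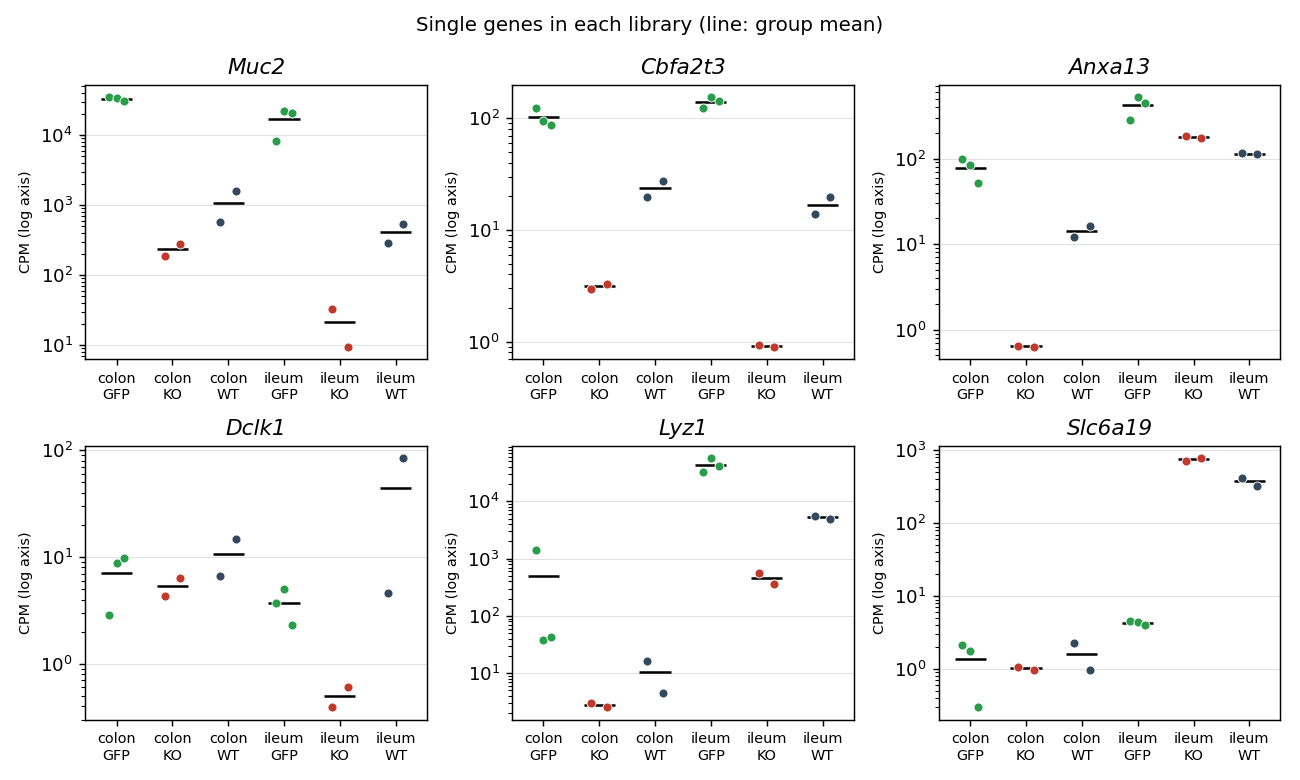
CPM on log axes for 6 genes, 1 point per library and a line at each group mean. Anxa13 was at 0.642 CPM on average in colon KO, Dclk1 at 84.4 CPM in ileum WT 2 and at 4.58 CPM in ileum WT 1, and Lyz1 at 1434 CPM in colon GFP 1.

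The last interaction asked where the enrichment of GFP-positive cells over WT crypts differed between colon and ileum. Several of the largest differences were in absorptive genes whose mean was far lower in sorted cells than in WT crypts in ileum but not in colon: Anpep (log2 difference 6.61, SE 0.83, edgeR adjusted p = 0.00169), Slc6a19 (6.34, SE 0.61, 0.000141) and Treh (6.06, SE 0.71, 0.000864). Anpep stood higher in the colon cells, at 63.8 ± 29.3 CPM in colon GFP and 12.5 ± 9.6 CPM in colon WT, against 194 ± 68.5 and 3690 ± 2240 CPM in ileum. Slc6a19 stood at 1.39 ± 0.965 CPM in colon GFP and 1.61 ± 0.916 CPM in colon WT, against 4.34 and 376 CPM in ileum. Of 28 absorptive genes 7 were higher and 1 lower (15 and 1 adjusted over the list alone; median 3.02, and 2.39 without colon GFP 1, which held ileal transcripts; adjusted p = 0.13 with an estimated correlation). Fut2 (3.49) was higher and Klf4 (−2.62) lower on the same scale. Proliferation genes were higher in 8 of 26 cases adjusted over the list alone (median 0.63, adjusted p = 0.367 with an estimated correlation). Goblet genes were lower in 2 of 20 (8 lower and 1 higher adjusted over the list alone; median −1.01, adjusted p = 0.487 with an estimated correlation; 8 without ileum GFP 1). In all 342 of 15274 genes were called, 203 higher and 139 lower. The count was 1093 with no filter on low counts, 840 with DESeq2, 155 with the 10 libraries of the groups compared, 138 without colon WT 2, 147 without colon WT 1, 188 without colon GFP 2, 205 without ileum GFP 2, 218 without ileum GFP 3 and 670 without ileum GFP 1.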

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

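Of the tests in this part, the one of cells in S phase was chosen after the result was seen.

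The effect of the knockout differed between colon and ileum for 1 gene by the interaction test, Anxa13 (log2 difference −5.15), with 0.651 and 0.633 CPM in colon KO, 12.0 and 16.2 CPM in colon WT, and 112 to 182 CPM in the ileum crypt libraries. The call was lost without colon KO 1 (edgeR adjusted p = 0.079) or colon KO 2 (0.0805), and the count was 313 without ileum WT 1 and 4 without ileum WT 2.

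The enrichment of sorted cells over WT crypts differed between the tissues for 342 genes by the interaction test (138 without colon WT 2, 147 without colon WT 1, 188 without colon GFP 2, 205 without ileum GFP 2, 218 without ileum GFP 3 and 670 without ileum GFP 1). The largest positive log2 differences were 9.81 for Pdzk1, 6.61 for Anpep, 6.34 for Slc6a19, 6.06 for Treh, 6.01 for Slc7a15 and 5.75 for Susd2. Pdzk1 had no count in colon WT and was at least 4.74-fold higher in colon GFP. The largest negative ones were −3.58 for Trim40, −3.64 for AW112010, −3.98 for Mfsd7a, −3.997 for B3galt2, −5.76 for Lyz2 and −5.78 for Casp14. With 2 counts each in ileum WT, the ileum GFP to WT ratio was 152 for B3galt2 (counting interval 42 to 1250) and 37.8 for Casp14 (10.5 to 313). B3galt2 lost its call without colon GFP 2 (edgeR adjusted p = 0.0669), colon GFP 3 (0.0527), colon WT 1 (0.0543), colon WT 2 (0.112), ileum WT 1 (0.102) or ileum WT 2 (0.111), without both WT 2 libraries and with the GC and length trend removed. Lyz2 lost its call without colon WT 2 (edgeR adjusted p = 0.0528) and with the replicate block (0.072), and Casp14 without ileum WT 1 (0.0509), with the block (0.0828) and without both WT 2 libraries.

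Reads outside genes, which no comparison used, were more frequent in sorted cells than in crypts. They made up 24.9, 31.9 and 30.0% of uniquely placed reads in colon GFP 1 to 3 and 52.3, 27.8 and 31.2% in ileum GFP 1 to 3, against at most 13.25% in any crypt library. In the same cells 20 of 24 histone genes in colon and 19 in ileum were higher than in WT crypts (medians 5.10 and 4.40), although histone genes share reads. More cells in S phase are argued against as the cause in ileum by the proliferation list, with 4 of 26 genes higher and 11 lower (median log2 fold change −0.40), while in colon 12 were higher and 4 lower (median 0.32) and a part stays open. Library preparation without poly(A) selection may account for the pattern, since 21 of 57 snRNA and snoRNA genes were higher in colon (median 1.24, quartiles −0.33 and 4.51) and 29 in ileum (median 1.99). The labels name no selection step, and other effects of sorting stay open.

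For colon against ileum sorted cells, the real grouping called 3471 genes and the highest of the other splits 1 gene. The 6 libraries allow 10 splits, the real one included, which are too few for a share under 0.05. Every other split also mixes colon and ileum libraries on each side, so tissue differences widen its spread. Its low count therefore does not show what chance alone would give.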

How the results depend on the processing

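Tests added after the data were seen were protein-coding genes only, removal of the GC and length trend, and leaving out both WT 2 libraries. The protein-coding set did not hold Anxa13, the 1 gene called for the KO effect by tissue, so that call could not be kept there. With the DESeq2 Wald test the calls numbered 157 for colon KO against WT, 496 for ileum KO against WT, 52 for the KO effect by tissue, 840 for GFP enrichment by tissue, 101 and 234 for genes lower in KO and higher in GFP in colon and ileum, and 100 for genes lower in KO in both tissues. With no filter on low counts these were 56 (colon KO), 9 (KO by tissue), 1093 (GFP enrichment), 34 (colon overlap) and 30 (both tissues). With only the libraries of the groups compared they were 102 (colon KO), 4 (ileum KO), 2147 (colon against ileum GFP), 1213 (colon against ileum WT), 155 (GFP enrichment), 66 and 3 (colon and ileum overlaps) and 3 (both tissues). With all 14 libraries in the fit they were 73 (colon KO), 265 (ileum KO), 1836 (WT tissues), 51 (colon overlap) and 49 (both tissues). Without both WT 2 libraries they were 108, 334, 51 (KO by tissue), 139 (GFP enrichment), 43 (colon overlap) and 48 (both tissues), and with protein-coding genes only the KO effect by tissue had 0 edgeR calls (516 at an unadjusted p under 0.05).

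Leaving out 1 library gave 0 (without colon KO 1 or 2; 791 and 624 at an unadjusted p under 0.05) to 14 genes for colon KO against WT, and 11 (without ileum KO 2) to 1348 (without ileum WT 1) for ileum KO against WT. It gave 0 (without colon KO 1 or 2) to 313 (without ileum WT 1) for the KO effect by tissue and 138 (without colon WT 2) to 670 (without ileum GFP 1) for GFP enrichment. It gave 4298 (without colon WT 1) to 7016 for colon GFP against WT and 1314 (without colon WT 2) to 3505 for colon against ileum WT. The overlaps ran from 0 (without colon KO 1 or 2) to 16 in colon, from 7 (without ileum KO 1 or 2) to 241 (without ileum WT 1) in ileum, and from 0 (without colon KO 1 or 2) to 71 (without ileum WT 1) for both tissues. These ranges are over the libraries of the groups compared. Ileum KO libraries enter colon KO against WT only through the shared estimate of the spread. Yet without ileum KO 1 or ileum KO 2 the colon calls of Cbfa2t3, Gfi1, Sytl2, Hpd, Slc12a8, Sval1, Txndc5 and Qpct were lost. DESeq2 size factors, library sizes without abundant genes and the GC and length correction left every count of calls within 1.5 times the main count. A share of 0.836 of the genes called in colon GFP against WT were still called in the same direction without the GC and length trend, which argues against that trend as their whole cause. Ileum GFP against WT, and GFP against KO in both tissues, stayed within 1.5 times under every alternative run.

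The replicate block gave 2 genes for the KO effect by tissue and 3231 for colon against ileum WT, where the numbers pair the samples; there it also ended the calls of Car1 and Defa24 (edgeR adjusted p = 0.0524 and 0.0862) and of no other gene named. For GFP enrichment, where the numbers pair the WT libraries but not the sorted ones, it gave 279 genes and ended the calls of Lyz2 and Casp14 (edgeR adjusted p = 0.072 and 0.0828). In the other comparisons the libraries share only a number. There the block gave 89 genes for ileum KO against WT, 65 for the ileum overlap, 19 for colon KO against WT and 3528 for colon against ileum GFP, where same-numbered pairs correlated at 0.009, −0.093 and 0.074. The date block for sorted cells gave 3216 genes and ended the calls named there of Car1, Retnlb, Fcgbp, Olfm4, Sis, Defa24, Defa22 and Lyz2 (edgeR adjusted p of 0.0573 to 0.234). Colon GFP 3 and ileum GFP 1 share their tag with no other library and do not enter that contrast. An effect of date can therefore not be told apart from the loss of these libraries or the ileal transcripts of colon GFP 1.

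Of the 10 comparisons per list, an estimated correlation left 0 camera calls of 9 for goblet, 9 for Paneth, 6 for enteroendocrine, 4 for tuft, 6 for deep crypt secretory, 10 for absorptive, 1 for stem, 5 for proliferation, 7 for secretory factors, 8 for ER, 7 for mucin glycosylation, 4 for antimicrobial, 4 for interferon, 7 for small intestine region, 6 for immune cells, 4 for stroma and 3 for dissociation lists, and 2 of 2 for colon region. Fry called 7 for goblet, 5 for Paneth, 5 for enteroendocrine, 0 for tuft and 6 for deep crypt secretory lists. It called 6 for absorptive, 1 for stem, 5 for proliferation, 5 for Notch (0 by camera) and 6 for secretory factors. ER had 5, mucin glycosylation 6, antimicrobial 4 and interferon 3 calls. Colon region, small intestine region, immune cell, stroma and dissociation lists had 4 each. In KO crypts the fry adjusted p was 0.0151 (colon) and 0.00406 (ileum) for goblet and 0.12 and 0.0224 for Paneth lists. In the same order it was 0.0114 and 0.00242 for enteroendocrine, 0.0236 and 0.0125 for secretory factor and 0.0272 and 0.0503 for ER lists. Fry does not compare a list with other genes. Of 222 values of 118 named genes, 200 were called; 122 kept their call under every alternative, 64 lost it without 1 library, and none reversed in 3180 alternative values (2866 the same, 277 weaker, 37 stronger). The cause of these changes was not tested, except that fewer libraries leave fewer degrees of freedom. Depth limits transcripts near the floor of 3 counts, and 30.02 to 44.88% of sorted-cell gene counts were mitochondrial ribosomal RNA.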

Other observations

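Of the tests in this part, those of ileal RNA or cells, of Paneth cells, of a mislabelled library and of immune cells were chosen after the results were seen; the type 2 list was written before its result was seen.

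Sorted cells held more RNA of secretory transcription factors than KO crypts. Of the 19 factors 11 were higher and 3 lower in colon (12 and 3 adjusted over the list alone; median log2 fold change 1.54, adjusted p = 0.311 with an estimated correlation). In ileum 16 were higher and 2 lower (median 2.50, adjusted p = 0.148). Genes that differed between colon and ileum overlapped between sorted cells and WT crypts, with 776 higher in colon in both (189 for independent lists) and 491 higher in ileum in both (144), while 27 and 28 went opposite ways.

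The WT 1 and WT 2 libraries differed in both tissues. All 15 tuft genes were higher in WT 2, with a median log2 ratio of 3.77 in ileum and 1.10 in colon. The resistin-like Retnlb stood at 12.1 and 750 CPM in ileum WT 1 and 2 and at 390 and 1167 CPM in colon, Clca1 at 2636 and 9409 CPM in colon, and Car1 at 6097 and 1477 CPM in colon. The secreted phospholipase Pla2g2a, named after its values were seen, stood at 213 and 462 CPM in colon and ileum KO 1, at 4.22 and 7.60 CPM in KO 2, at 24.7 and 64.4 CPM in WT 1 and at 475 and 7429 CPM in WT 2.

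Tuft genes in ileum WT 2 (Dclk1 at 84.4 CPM, against 4.58 CPM in ileum WT 1) were weighed further. A mislabelled KO library is argued against by Atoh1, which was 38.9 times the highest ileum KO library, and more immune cells by the immune list, with a median log2 ratio of −3.07. A type 2 immune response in this animal is a candidate explanation that stays open: the type 2 list, with a median of 0.37, lay at percentile 99.5 of 10000 random lists, and 7 of its 11 genes were higher. The largest rises were in Ang4 (267 and 5170 CPM), which the Paneth list also holds, and Sprr2a3 (38.2 and 216 CPM). The median itself was the ratio of Sprr2a2, at 1.53 and 2 CPM. The other genes that were higher were weak: Sprr2b (1.07 and 2.75 CPM), Arg1 (0.915 and 1.25), Sprr2a1 (0.229 and 0.416) and Cpa3 (0.229 and 0.25). The percentile therefore rests on genes with few counts. Mcpt1, Mcpt2, Il4ra and Il13ra1 were lower, the colon percentile was 20.7, and the goblet, Paneth and deep crypt lists lay at percentile 100 too. The design names no group for it, so no biological explanation beyond that list was tested. Ileum WT 2 also differed from ileum WT 1 in lists of other cells. Stroma genes had a median log2 ratio of −2.385 (2 of 21 higher in WT 2) and absorptive genes −0.313 (8 of 28 higher). The cause of these wider differences was not tested.

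Colon GFP 1 held transcripts of the ileum. In colon GFP 1, 2 and 3, Lyz1 stood at 1434, 37.8 and 42.0 CPM, Defa24 at 308, 4.24 and 2.84 CPM, Lgals2 at 361, 22.4 and 25.7 CPM and Apoa1 at 28.8, 0.374 and 0.150 CPM, genes named after their values were seen. RNA or cells from the ileum may account for this: a share of 0.914 (32 of 35) of the ileum-specific genes other than Paneth list members and named defensins were highest in that library, against 47.3% of 5972 background genes, where 1 in 3 had been assumed. The same share argues against Paneth-like cells in this colon as the whole cause; it was 28 of 31 without genes that have no name, some of which may be further defensins, and 4 of 4 for absorptive list members, while 18 of the 19 Paneth and defensin genes were highest there. Colon GFP 1 shares a date tag with ileum GFP 2, as colon GFP 2 does with ileum GFP 3, and the excess was no single fraction of either ileum reference, at medians of 7.56% (35 genes) and 2.06% (19 genes) of ileum GFP but 3.84% and 12.2% of ileum crypts, so the source and the step at which it entered stay open.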
